A study of Mus musculus with 8 samples.

How the data were processed

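RNA was measured in bone marrow cells of mice aged 6 weeks, in 4 groups of 2 arrays each. KSL cells are the c-Kit positive, Sca-1 positive, lineage negative fraction, which holds haematopoietic stem and progenitor cells. Gr cells are the Gr-1 and Mac-1 positive fraction, which holds granulocytes and their late precursors. Each cell type came from control mice and from Vav-Etv2 mice, in which a transgene of Etv2, an ETS transcription factor that specifies blood and endothelial precursors in the embryo, is turned on by Cre recombinase under the Vav promoter, which is active in blood cells. Per the labels, total RNA from sorted cells was labelled with Cy3 after amplification from low input, and the strain background was mixed. All 8 arrays lay on 1 slide read in 1 scan, with the KSL samples on slide row 1 and the Gr samples on slide row 2, so a difference between slide rows and a difference between cell types cannot be told apart. The labels do not say whether the arrays are separate animals or pools, so the p-values measure only the spread between these samples.

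Per the file headers, the deposited array files hold fluorescence intensity extracted with Agilent Feature Extraction 10.7.3.1 (10.7 in the submitters' processing notes). The column used here is the processed signal, an intensity that was background-subtracted and spatially detrended, was not normalised between arrays, and carries a surrogate value where a spot is near or below background. The deposited raw intensity columns, the mean spot signal and the median local background, were used for 1 alternative. The deposited quality columns hold other values, marks of 0 or 1 per spot for outliers, saturation, control spots and signal well above background. The deposited value table holds log2 values. Checked against the signals, these were the processed signals scaled per array and then centred on each probe's median within each cell type, and 99.7% of its values lay within 0.01 log2 of those recomputed here. Levels of KSL and Gr cells therefore cannot be compared in that table, and it served only as an alternative for comparisons within a cell type.

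Each array held 62976 spots, of which 59305 were not controls and gave 55681 distinct probes. Spots marked as non-uniform outliers were removed, the remaining spots of a probe were averaged, and 20 probes with no spot left on at least 1 array were left out. Probes were named through the transcript accessions in the files and the gene annotation (26582 probes), the current symbol (2602) or an older symbol (492), and 26005 kept the name in the file. Probe coordinates are those of the files, on build mm9. Signals were put on the log2 scale, and each array's 75th percentile over non-control probes was subtracted. Probes had to be well above background on at least 2 of the 8 arrays, whichever group these belonged to. Of the 32352 that passed, the probe with the highest mean over all 8 arrays stood for its gene, which left 23231 features for testing, 9269 of them with names of gene models or clones.

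The 75th percentile of the signal was 195 and 266 in KSL control replicates 1 and 2, 213 and 216 in the KSL Vav-Etv2 replicates, 136 and 301 in the Gr control replicates and 149 and 273 in the Gr Vav-Etv2 replicates. Between 47.7% and 55.5% of probes were well above background, and 0 were saturated. Repeat spots of a probe within an array had a median SD between 0.0590 and 0.0697 log2. The SD of the difference between replicates over all features was 0.556 log2 in KSL controls, 0.896 in KSL Vav-Etv2 cells, 1.05 in Gr controls and 0.961 in Gr Vav-Etv2 cells. The number of arrays limits the precision.

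A linear model with 1 coefficient per group was fitted to all 8 arrays with limma 3.58.1 (lmFit and eBayes) in R 4.3.3, and the files were read with version 1.17.8 of data.table. The 4 groups shared 1 estimate of the spread, with 4 residual degrees of freedom and 2.77 prior degrees of freedom. Vav-Etv2 was compared with control within KSL and within Gr cells. The difference of these effects (the interaction) and control KSL against control Gr cells were tested in the same model. A gene was called at a Benjamini-Hochberg adjusted p under 0.05. SE is limma's moderated standard error of the log2 difference. Where neither array of the lower group was well above background, a fold is given as a lower bound, computed with signals under each array's lowest well-above-background signal raised to that signal.

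The tests, the alternatives, the naming rule and 25 gene lists were fixed before the data were examined. The lists were endothelial, vascular and blood transcription factors, Notch and angiogenic signalling, haematopoietic stem cell, lymphoid priming, B lineage, T and NK cell, erythroid, megakaryocyte and platelet, primary granule and early myeloid, secondary granule and mature neutrophil, monocyte and macrophage, dendritic cell and MHC class II, mast cell basophil and eosinophil, bone marrow stroma, proliferation, CDK inhibitors and quiescence, p53 targets and apoptosis, interferon response, inflammatory and NF-kB, immediate early and handling stress, adhesion and homing, glycolysis and hypoxia, oxidative phosphorylation, and sex-linked. Each list was tested with limma's camera at a preset correlation between genes of 0.01, adjusted over the 25 lists, and again with the correlation estimated from these arrays. fry was run beside it, adjusted over the 25 lists in the same way (a step added after its unadjusted p values were seen), and tests whether a list's genes move, on balance, in 1 direction, without comparing them with other genes. The lists singled out for the checks of stability (endothelial, haematopoietic stem cell and B lineage in KSL cells; B lineage, MHC class II and T and NK cell in Gr cells) were picked after the results were seen.

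Named genes follow a rule. For each Vav-Etv2 comparison it takes Etv2, up to 12 largest rises and 12 largest falls among called genes whose groups do not overlap, and up to 4 members per list with the lowest p. For the interaction and for control KSL against Gr it takes up to 8 in each direction, and names of gene models and clones are left out. Where fewer than 5 genes were called in a direction, the 5 with the lowest p are named as not past the threshold. Kit, Ly6a, Itgam and Ly6g, the markers of the sorts, were also fixed, and Ly6g had no feature on the array. Features outside the rule that are named below (3 immunoglobulin features known only by transcript identifiers, Cdh5, Sox18, Kdr, Ifi202b, Jchain, Igf2bp3, Bmpr1a, and the genes named from the model with a sex term) were chosen after their values were seen.

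Alternatives were median scaling, quantile normalization, normexp background correction with an offset of 50 on the raw signals, the deposited value table, no filter and a filter on all 8 arrays, a floor on dim signals, the mean of a gene's probes, each probe by itself, only the arrays of the groups compared, an intensity trend in eBayes, a block for the replicate number, a threshold that adds a change of at least 2-fold, and leaving out each array in turn. 3 were added after the data were seen: a sex term for the 2 Gr arrays with Y-linked signal, leaving out those 2 arrays, and leaving out KSL Vav-Etv2 replicate 1 with the array labelled Gr control 2. Replicate numbers are shared between groups, but nothing in the labels pairs the samples. The model was tested on simulated data with 23231 genes, the real spread and 2 arrays per group. In the simulated KSL comparison it recovered 0% of genes changed by 1 log2, 13.4% of those changed by 2 and 66.7% of those changed by 4, with 0 false calls. In the simulated Gr comparison it recovered 11.9% and 63.6% of those changed by 2 and 4. A simulated list of 20 genes shifted by 1 log2 was called in both, with 0 other lists. The simulated genes varied independently and the lists were random. The simulation therefore cannot show how often camera calls a list falsely when its genes vary together.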

Results

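Etv2, the gene the transgene carries, was measured by 2 probes on chromosome 7 of build mm9, and the one used for the gene spans positions 31419633 to 31419692. Levels are log2 values relative to the array's 75th percentile. In KSL cells Etv2 stood at -4.37 and -4.73 in the controls, neither well above background, and at 0.19 and -1.24 in Vav-Etv2 replicates 1 and 2, a level at least 12.4-fold higher (log2 difference 4.02, SE 1.19, n = 2 and 2, limma adjusted p = 0.460, not past the threshold). In Gr cells Etv2 stood at -0.55 and -1.30 in the Vav-Etv2 replicates, at -4.48 in Gr control 1, not well above background, and at -0.55 in the array labelled Gr control 2, where it was well above background. The Gr difference was 1.59 (SE 1.19, limma adjusted p = 1.00). Without the array labelled Gr control 2 it was at least 2.87, and without Gr control 1 it was -0.38. The other Etv2 probe, at positions 31418776 to 31418835, read -5.81, not well above background, in Gr control 1. It read -2.33 and -1.88 in the Gr Vav-Etv2 replicates and -0.85, above both, in the array labelled Gr control 2. Every Gr difference below uses that array under its label. Whether either probe lies within the transgene is not known from the labels.

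**Figure D1:**
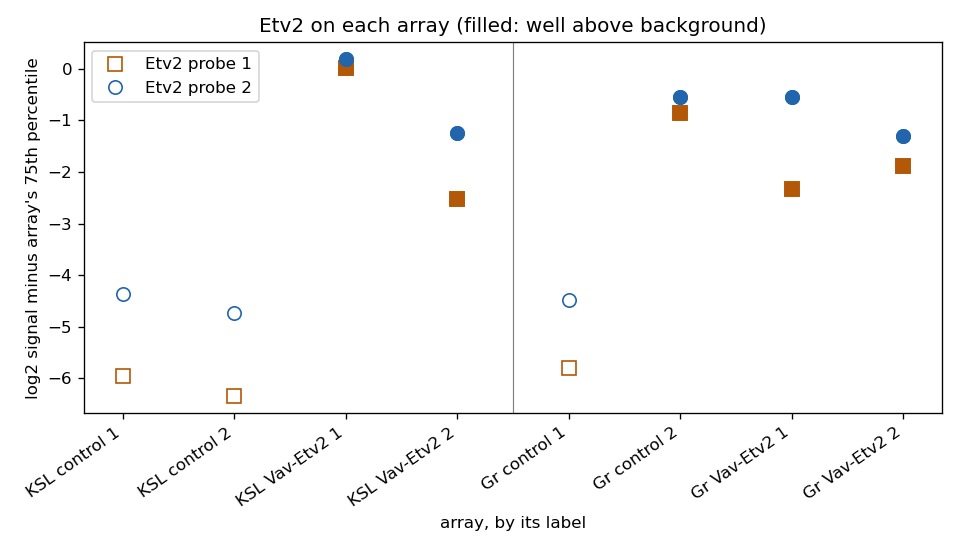
Etv2 level (log2, relative to the 75th percentile of the array) for both probes on each of the 8 arrays, with filled points where the probe was well above background. The array labelled Gr control 2 reads -0.55 and -0.85, in the range of the Vav-Etv2 arrays of both cell types. The -0.85 is above both Vav-Etv2 Gr arrays for that probe (-2.33 and -1.88).

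In Vav-Etv2 KSL cells 3 immunoglobulin features fell and 1 gene, Sva, rose. ENSMUST00000103403, an immunoglobulin kappa segment, was at least 279-fold lower than in controls (log2 difference -9.22, SE 0.59, limma adjusted p = 0.0116). ENSMUST00000103416, from the constant region of the IgG2c heavy chain, fell by 5.42 (SE 0.34, limma adjusted p = 0.0116), from 4.50 and 4.37 in the controls to -1.03 and -0.94. ENSMUST00000103414, described as a predicted gene in the files, was at least 47.3-fold lower (log2 difference -6.75, SE 0.27, limma adjusted p = 0.00131). Sva, which encodes a secreted seminal vesicle antigen, rose from -4.83 and -3.91 in the controls to 0.71 in both Vav-Etv2 replicates (log2 difference 5.08, SE 0.42, limma adjusted p = 0.0447), and 1 of the 2 controls was well above background. The features lie on mm9 chromosome 6 at 70648995 to 70649054, chromosome 12 at 114525600 to 114525659, chromosome 12 at 114509504 to 114509563 and chromosome 6 at 41992738 to 41992797, in the order named. The 3 immunoglobulin features were singled out after their values were seen. In all, 1 gene rose and 3 fell among 23231, and 1723 had an unadjusted p under 0.05, where chance gives 1162.

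Leaving out single arrays changed these calls. Without KSL control 1 there were 2 calls, without KSL control 2 there were 0 (limma), without KSL Vav-Etv2 1 there was 1, without KSL Vav-Etv2 2 there were 36, and without Gr control 1 or the array labelled Gr control 2 there were 11. Sva lost its call whichever of the 8 arrays was left out (limma adjusted p from 0.0541 to 0.402). ENSMUST00000103414 lost it only without KSL control 2 (limma adjusted p = 0.0651). ENSMUST00000103403 and ENSMUST00000103416 lost it without KSL control 1 (0.140 and 0.165), KSL control 2 (0.144 for both) and KSL Vav-Etv2 1 (0.177 for both). With only the KSL arrays fitted, ENSMUST00000103403 (limma adjusted p = 0.0513) and Sva (0.0911) were lost, and Sva was also lost with no filter (0.0546) and with each probe by itself (0.0591).

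Other genes had large differences that did not pass. Ifi214, of the interferon-inducible Ifi200 family, was at least 33.1-fold higher in Vav-Etv2 KSL cells (log2 difference 5.78, SE 0.54, limma adjusted p = 0.0570). Tmem255a was at least 5.34-fold higher (4.23, limma adjusted p = 0.0581), the sodium channel subunit Scn4b differed by 4.06 (0.0756) and Rgs21, a regulator of G protein signalling, was at least 2.02-fold higher (0.110). On the lower side were the imprinted non-coding RNA Meg3 (-2.71, SE 0.30, limma adjusted p = 0.0756), the olfactory receptor Olfr370 (at least 5.41-fold lower, 0.0756), Npdc1 (-4.28, 0.0756), the TGF-beta binding protein Vasn (at least 7.68-fold lower, 0.0786) and the kappa segment Igkv5-39 (-9.06, 0.0786). Ifi214 was called without Gr control 1 or the array labelled Gr control 2, Scn4b without either Gr Vav-Etv2 array, and Igkv5-39 without KSL Vav-Etv2 2.

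The haematopoietic stem cell list was lower in Vav-Etv2 KSL cells. Of its 30 measured genes 26 had a negative difference, the median was -0.74, 0 rose and 0 fell over all genes, and 3 fell when adjusted over the list alone. Camera gave an adjusted p of 9.38e-07, with adjusted p = 0.0908 with an estimated correlation, and fry gave an adjusted p of 0.0415. Hoxb5, a transcription factor of long-term stem cells, was at least 6.21-fold lower (-3.70, SE 0.57, limma adjusted p = 0.146), the cell-cycle inhibitor Cdkn1c differed by -1.52 (0.213), the transcription factor Hlf by -3.03 (0.319) and the stem cell surface protein Procr by -2.12 (0.431). The list was lower in both Vav-Etv2 replicates against the mean of the controls, with medians of -0.95 and -0.68. It also holds the sort markers Kit and Ly6a, which were 2.40-fold and 1.93-fold lower in Vav-Etv2 KSL cells, neither past the threshold. Whether the sort took the same kinds of cells from both genotypes was not tested.

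The B lineage list was higher, with 14 of 15 measured genes positive, a median of 1.68, 0 genes past the threshold over all genes and 6 that rose when adjusted over the list alone. Its camera adjusted p was 1.21e-07, and adjusted p = 0.780 with an estimated correlation, and fry gave an adjusted p of 0.730. The surrogate light chain genes Vpreb1 (log2 difference 3.45, SE 0.88, limma adjusted p = 0.356) and Igll1 were 10.9-fold and 13.5-fold higher, and the B lineage factor Pax5 was at least 3.43-fold higher. Both Vav-Etv2 replicates were above the control mean, with list medians of 1.50 and 2.45.

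The endothelial list was higher overall but unevenly between the replicates. Of 35 measured genes 28 were positive with a median of 0.94, 0 rose and 0 fell either over all genes or adjusted over the list alone, and camera gave an adjusted p of 6.40e-06, with adjusted p = 0.780 with an estimated correlation, and fry gave an adjusted p of 0.730. The list median was 2.19 in KSL Vav-Etv2 1 and 0.11 in KSL Vav-Etv2 2, and camera gave 0.0465 without KSL Vav-Etv2 1. Against the control mean, the VEGF receptor Flt1 stood 6.61 higher in replicate 1 and 1.55 in replicate 2, the transcription factor Sox18 6.19 and 1.64, and the junction protein Cdh5, well above background in 1 of the 2 controls, 7.23 and 2.11. The phosphatase Ptprb stood at 2.61 and -1.82 and was not well above background in either control, which makes it at least 23.5-fold higher. The VEGF receptor Kdr, at levels of 3.37 and 3.13, differed from the control mean by -0.03 and -0.27. Flt1 passed the threshold without KSL Vav-Etv2 2, where its difference was 6.61.

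Further lists differed in KSL cells by camera at the preset correlation, with 0 genes past the threshold over all genes or adjusted over the list alone by limma and fry adjusted p from 0.730 to 0.747. The mature neutrophil list was lower (23 measured, 21 negative, median -1.48, adjusted p = 0.00123, and adjusted p = 0.780 with an estimated correlation), with log2 differences of -2.36 for the granule gene Camp and -2.57 for Lcn2. Its median was -3.38 in KSL Vav-Etv2 1 and 0.31 in KSL Vav-Etv2 2, and without KSL Vav-Etv2 1 its direction turned to higher (0.0810). The immediate early and handling stress list was lower (18 measured, median -0.88, adjusted p = 0.00684, and adjusted p = 0.780 with an estimated correlation), with a log2 difference of -1.66 for Fosb, and gave 0.311 without KSL Vav-Etv2 1. The proliferation list was higher in all 25 measured genes (median 0.23, adjusted p = 0.0195, and adjusted p = 0.781 with an estimated correlation), with a log2 difference of 0.44 for the mitotic kinase Plk1, and lost its call without KSL control 1 (0.269), without KSL Vav-Etv2 2 (0.0863) and under median scaling (0.0546). The T and NK cell list was lower (18 measured, median -0.34, adjusted p = 0.0385, and adjusted p = 0.780 with an estimated correlation), with a log2 difference of -3.10 for the T cell receptor subunit Cd3g. It lost its call without KSL control 1 (0.0741), KSL control 2 (0.0857), KSL Vav-Etv2 1 (0.0810) or either Gr Vav-Etv2 array (0.0595), and under normexp (0.0603), quantile normalization (0.0577), no filter (0.127), the filter on all 8 arrays (0.210) and only the KSL arrays (0.0952). The monocyte and macrophage list was higher (22 measured, median 0.34, adjusted p = 0.0385, and adjusted p = 0.780 with an estimated correlation), with a log2 difference of 3.33 for the chemokine receptor Ccr2, and lost its call without KSL control 1 (0.138) or KSL Vav-Etv2 2 (0.967), and under median scaling (0.0546), quantile normalization (0.0577) and the filter on all 8 arrays (0.0746).

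The other 17 lists had camera adjusted p from 0.191 to 0.929 in KSL cells. They were vascular and blood transcription factors, Notch and angiogenic signalling, lymphoid priming, erythroid, megakaryocyte and platelet, primary granule, MHC class II, mast cell basophil and eosinophil, stroma, CDK inhibitors, p53 targets, interferon response, NF-kB, adhesion and homing, glycolysis and hypoxia, oxidative phosphorylation, and sex-linked genes. Adjusted over the list alone, 1 gene fell in each of the vascular factor, lymphoid priming, stroma and CDK inhibitor lists and 2 in the Notch list. Without KSL Vav-Etv2 2 the primary granule, MHC class II, mast cell, stroma and NF-kB lists were called (0.0420). The median and the test differed in sign for the megakaryocyte list (median 0.03, direction down), and the mean and the test for the Notch list (mean 0.01, direction down).

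**Figure D2:**
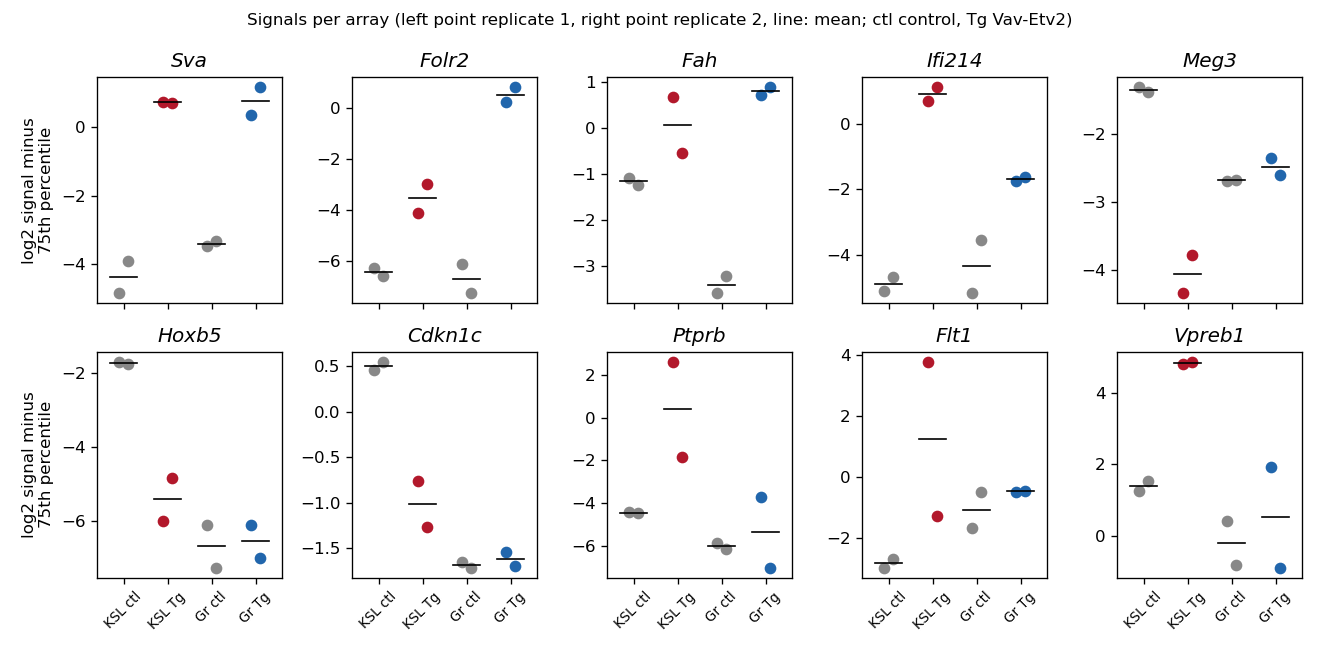
Level (log2, relative to the 75th percentile of the array) of 10 named genes on each of the 8 arrays, with points for arrays and lines for group means. Sva is higher on all Vav-Etv2 arrays of both cell types than on the controls.

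In Vav-Etv2 Gr cells the folate receptor gene Folr2 rose and ENSMUST00000103416, the IgG2c heavy chain feature, fell. Folr2 (mm9 chromosome 7, 108988771 to 108988830) was at least 29.7-fold higher (log2 difference 7.20, SE 0.54, n = 2 and 2, limma adjusted p = 0.0474), at 0.24 and 0.81 against -6.11 in Gr control 1 and -7.25 in the array labelled Gr control 2. ENSMUST00000103416 was at least 51.0-fold lower (log2 difference -5.95, SE 0.34, limma adjusted p = 0.0167) and was the only call shared with KSL cells. At an unadjusted p under 0.05 there were 295 genes, fewer than the 1162 that chance gives. Among the Gr arrays 173 genes were at least 4-fold apart between the replicate numbers and 13 between the labelled genotypes. The model has no replicate term, so that difference enters its spread and can lower such counts. The shortfall therefore does not measure how small the Vav-Etv2 effect is. Both calls were lost whichever of the 8 arrays was left out, with limma adjusted p from 0.0632 to 0.448 for Folr2 and from 0.0555 to 0.181 for ENSMUST00000103416. Folr2 also lost its call under normexp (limma adjusted p = 0.352), the floor (0.125), no filter (0.0522), each probe by itself (0.0601) and the intensity trend (0.0501). The replicate block (0.191) and only the Gr arrays (0.222) ended it as well. ENSMUST00000103416 lost its call under normexp (limma adjusted p = 0.101), the replicate block (0.0844) and only the Gr arrays (0.222). The count was 0 by limma without any 1 array other than Gr Vav-Etv2 2, and without that array 2 other genes rose.

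The Gr arrays also differed in sex-linked RNA. The X-inactivation RNA Xist stood at 0.27 and 0.35 in the replicate 1 arrays and at -7.10 and -6.83 in the replicate 2 arrays, and the Y-linked Ddx3y at 1.38 and 1.36 in the latter. All 4 KSL arrays had Xist between 2.12 and 2.69. In Gr cells the split by sex is also the split by replicate number. The 75th percentile of the signal was 136 and 149 in the replicate 1 arrays and 301 and 273 in the replicate 2 arrays. From replicate 1 to 2 the median of the mast cell list rose by 2.62 in controls and 3.24 in Vav-Etv2 cells. Sex thus cannot be told apart from these differences, and within-sex below means within a replicate number. Within each sex Folr2 was at least 4.03 and 5.75 log2 higher in Vav-Etv2 than in control cells, and the bounds for ENSMUST00000103416 were -4.98 and -6.36. With a sex term neither was called (limma adjusted p = 0.296 and 0.0561). Across all genes the within-sex differences correlated at r = 0.0517, a value across genes, which are not independent replicates.

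Sva was higher in Gr cells too, by 4.14 (SE 0.42, limma adjusted p = 0.189, within-sex differences 3.82 and 4.47), as was Fah, an enzyme of tyrosine breakdown, by 4.21 (0.189, within-sex 4.32 and 4.10). Neither passed, nor did Commd10 (2.65) and Fam78b (at least 2.53-fold higher). On the lower side Arhgef25 (at least 2.01-fold lower), the NK receptor Klrb1a (at least 1.66-fold lower), the keratin Krt8, the growth factor Bmp7 and Zbed5 did not pass. The last 3 were not well above background in either Vav-Etv2 array, and no bound can be given for them.

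The B lineage list was higher in Gr cells, with all 15 measured genes positive, a median of 0.73 and a camera adjusted p of 1.94e-04, with adjusted p = 0.848 with an estimated correlation. No gene passed over all genes or adjusted over the list alone, and the receptor subunit Cd79b differed by 0.98 and the adaptor Blnk by 0.87. The within-sex list medians were 1.56 and 0.01. Without the array labelled Gr control 2 camera gave 0.635, and without Gr Vav-Etv2 1 the direction turned to lower (0.0405). The MHC class II list was higher (13 measured, 11 positive, median 0.56, adjusted p = 1.94e-04, and adjusted p = 0.467 with an estimated correlation), with log2 differences of 0.75 for the antigen presentation gene Cd74 and 0.56 for H2-Ab1 and within-sex medians of 0.59 and 0.39, and gave 0.0586 without Gr control 1. The fry function of limma gave an adjusted p of 0.997 for both lists.

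The T and NK cell list was lower in Gr cells (18 measured, 14 negative, median -0.37, camera adjusted p = 0.00172, and adjusted p = 0.848 with an estimated correlation), and 1 gene fell when adjusted over the list alone. The cytokine receptor subunit Il2rb differed by -1.47 and the protease Gzma by -2.04, and the within-sex list medians were -0.40 and -0.47. Camera gave 0.233 without Gr control 1 and 0.563 without Gr Vav-Etv2 2. The monocyte and macrophage list was higher (22 measured, 18 positive, median 0.39, adjusted p = 0.0102, and adjusted p = 0.848 with an estimated correlation), with a log2 difference of 1.14 for the sialic acid receptor Siglec1 and within-sex medians of 0.85 and 0.17. It lost its camera call without Gr control 1 (0.947), Gr Vav-Etv2 1 (0.137) or Gr Vav-Etv2 2 (0.0507). The fry function of limma gave an adjusted p of 0.997 for these 2 lists as well. The other 21 lists had camera adjusted p of 0.0786 or more, with 0.178 for the endothelial list and 0.603 for the stem cell list. Among these other lists, leaving out single arrays added calls. Without either KSL Vav-Etv2 array the endothelial list was called as higher (0.0241) and the erythroid list as lower (0.0433), and without the array labelled Gr control 2 the erythroid list as lower (0.0492) and the proliferation list as higher (0.0102). Without Gr control 1 (6.07e-05 to 0.0316) the lymphoid priming, megakaryocyte, stroma, immediate early and glycolysis lists were called as higher and the primary granule, mast cell and proliferation lists as lower. Without Gr Vav-Etv2 1 (1.46e-05 to 0.0414) the proliferation and oxidative phosphorylation lists were called as higher and the erythroid, megakaryocyte, neutrophil, NF-kB and immediate early lists as lower. Without Gr Vav-Etv2 2 (1.43e-04 to 0.0385) the endothelial, lymphoid priming, megakaryocyte, stroma, interferon, immediate early and glycolysis lists were called as higher and the primary granule, mast cell, proliferation and oxidative phosphorylation lists as lower. The megakaryocyte, proliferation, immediate early and oxidative phosphorylation lists thus went both ways. Other settings also added calls, for the erythroid list under normexp (0.0121), median scaling (0.0308), no filter (0.0414), the filter on all 8 arrays (0.0194), the mean of probes (0.0188) and only the Gr arrays (0.0334), and for the endothelial list with only the Gr arrays (0.0148). The lymphoid priming list was called under normexp (0.0220), the floor (0.0497) and the sex term (0.0167), the primary granule list under normexp (0.0102) and the sex term (0.00584), the glycolysis list under normexp (0.0128) and the mast cell list under the sex term (0.0139). The median and mean of the Notch list were above 0 and its test pointed down, and the adhesion list had a median of -0.002 with its test pointing up.

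**Figure D3:**
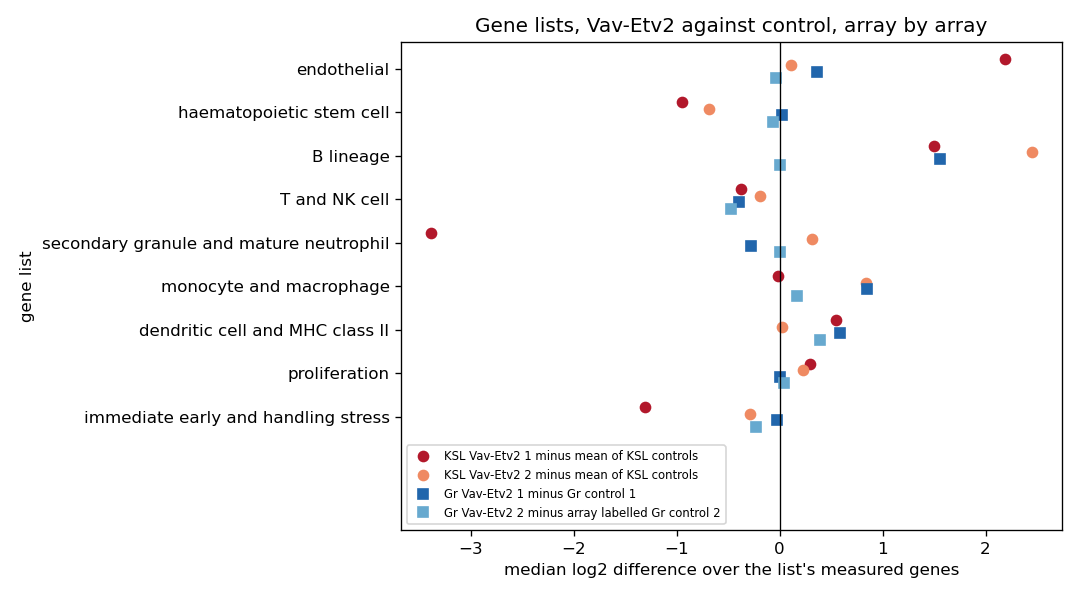
Median log2 difference over the measured genes of 9 lists, for each KSL Vav-Etv2 array against the control mean and for each Gr pair of 1 sex. The endothelial and neutrophil lists are far from 0 in KSL Vav-Etv2 1 alone, at 2.19 and -3.38.

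The difference of the Vav-Etv2 effect between KSL and Gr cells passed for 1 feature, ENSMUST00000103414 (fitted difference of effects -6.57, SE 0.38, limma adjusted p = 0.0159). It was well above background on 0 of the 4 Gr arrays, so it could not fall in Gr cells and the difference restates its fall in KSL cells. It lost this call whichever array was left out, and also under normexp (limma adjusted p = 0.428), the floor (0.169), no filter (0.0521) and the intensity trend (0.101). The replicate block (0.0557) and the replicate block within genotype (0.281) ended the call too. The 906 features with an unadjusted p under 0.05 were fewer than the 1162 that chance gives. Here too the spread holds the difference between the Gr replicates. Scn4b (3.68), Meg3 (-2.92, 0.502), the ubiquitin ligase Mid1 (-5.67, 0.396) and Etv2 (2.43, SE 1.68, limma adjusted p = 1.00) did not pass, nor did Tmem255a (0.502) and Hoxb5 (0.958), both well above background on 0 of the 4 Gr arrays. The stem cell list was lower in KSL relative to Gr cells (median of differences -0.77, camera adjusted p = 1.64e-05, and adjusted p = 0.121 with an estimated correlation, fry adjusted p = 0.0643). Its median level was 2.19 and 2.28 in the KSL controls and -2.72 and -2.80 in the Gr controls. Members at background in Gr cells, such as Hoxb5, could not fall there, so part of this difference may restate the fall in KSL cells. The endothelial list was higher (0.63, 0.0103, and adjusted p = 0.980 with an estimated correlation), and lost its call without KSL Vav-Etv2 1 (0.701), Gr control 1 (0.0741) or Gr Vav-Etv2 2 (0.364) and with the filter on all 8 arrays (0.0788). Without the Gr arrays with Y-linked signal it had 0.524 and the B lineage list 0.440. The B lineage list was higher (0.99, 0.0113, and adjusted p = 0.980 with an estimated correlation), lost its call without KSL Vav-Etv2 2 (0.280) or Gr control 1 (0.200), and turned to lower without Gr Vav-Etv2 2 (0.944). The fry function of limma gave these 2 lists an adjusted p of 0.987. The other 22 lists had camera adjusted p of 0.0509 or more. Leaving out single arrays added calls among them. Without KSL control 1 the neutrophil list was called as lower (0.0361), and without KSL control 2 the stroma list as lower (0.0302) and the proliferation list as higher (0.0451). Without KSL Vav-Etv2 1 (0.0270 for each) the neutrophil and monocyte lists were called as higher and the Notch and megakaryocyte lists as lower, and without KSL Vav-Etv2 2 (8.97e-15 to 0.0404) the neutrophil, stroma and immediate early lists as lower. Without Gr control 1 (1.45e-05 to 0.0125) the proliferation list was called as higher and the neutrophil, stroma and immediate early lists as lower. Without Gr Vav-Etv2 1 the erythroid list was called as higher (0.00611). Without Gr Vav-Etv2 2 (1.41e-04 to 0.0381) the proliferation and oxidative phosphorylation lists were called as higher and the lymphoid priming, megakaryocyte, neutrophil, stroma and immediate early lists as lower. The neutrophil list was also called under normexp (0.00545), median scaling (0.0196), the filter on all 8 arrays (0.0266), the mean of probes (0.0307) and the replicate block within genotype (0.0401), the immediate early list under normexp (0.00339), median scaling (0.0458), the filter on all 8 arrays (0.0402) and the sex term (0.0215), and the proliferation list under the sex term (0.00724).

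Across all genes the KSL and Gr effects had r = 0.129 and rho = -0.043, and 45.8% had the same sign, values across genes that are not independent. r was 0.0217 without Gr control 1 and 0.0113 without Gr Vav-Etv2 2. The single shared fall compares with 0.000129 expected by chance (Fisher's exact test, one-sided, p = 0.000129). At an unadjusted p under 0.05 in both cell types 29 genes were higher in both, where 4.45 are expected by chance, and 49 were lower in both, where 6.57 are expected (Fisher's exact test, one-sided, p = 6.57e-16 and p = 1.72e-29). In opposite directions there were 7 higher in KSL and lower in Gr cells (5.00 expected) and 16 the other way (5.86 expected). These tests take genes as independent, and both effects use 1 estimate of each gene's spread, which raises overlaps in any direction.

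Between control KSL and control Gr cells 3778 genes were higher in KSL and 4286 lower, 34.7% of those tested. Dntt, the polymerase of lymphoid precursors, differed by 8.58 (SE 0.65, limma adjusted p = 9.16e-04), the myosin light chain Myl10 was at least 876-fold higher, the kappa segment Igkv5-39 at least 284-fold, the sugar transporter Slc35d3 at least 70.8-fold and the growth factor receptor Pdgfrb at least 58.2-fold. Lower in KSL were the chemokine receptor Ccr1l1, at least 53.2-fold, the lipid droplet protein Plin5, at least 46.7-fold, and the myeloid receptor Tarm1, at least 24.5-fold. Of the sort markers Kit differed by 3.21 (SE 0.38, limma adjusted p = 0.00256), while Ly6a (-1.70, 0.122), which encodes Sca-1, and Itgam (-1.60, 0.0596), which encodes Mac-1, did not pass. Without the array labelled Gr control 2 their differences were -2.56 and -2.19. The direction of Itgam goes with the sort. Ly6a read lower in the cells sorted as Sca-1 positive, so its RNA does not bear out the sort, and the reason was not tested. The count was 2240 without KSL control 1, 2201 without KSL control 2 and 4020 without Gr control 1. Etv2 was at least 3.12-fold lower (log2 difference -2.04, 0.216), and the call was gained without Gr control 1, where it was at least 3.61 log2 lower. Without the array labelled Gr control 2 no array of either group was well above background. The median of all genes was -0.133 and moved to -0.30 under median scaling.

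In the stem cell list 23 of 30 genes were higher in KSL controls over all genes and 23 adjusted over the list alone, 0 were lower, and the median was 4.24, or 3.43 with 6 genes at their lower bound (camera adjusted p = 4.38e-09, and adjusted p = 0.0480 with an estimated correlation, the only call kept). The progenitor genes Cd34 (6.31) and Meis1 (5.84) were among them. The endothelial list had 16 higher and 2 lower (median 2.02, 1.56 with bounds, 1.10e-04), the T and NK cell list 9 and 1 (1.68, 0.96 with bounds, 0.00422), the erythroid list 7 and 1 (1.28, 0.00993), the megakaryocyte list 9 and 1 (2.81, 0.0285), the lymphoid priming list 8 and 3 (1.99, 0.0322) and the B lineage list 3 and 0 (1.38, 0.0322). The mature neutrophil list had 0 higher and 14 lower (-4.47, -4.08 with bounds, 5.83e-06), the monocyte list 0 and 10 (-2.22, 1.10e-04, with a log2 difference of -5.55 for Lyz2), the NF-kB list 0 and 9 (-1.35, 0.0202) and the interferon list 3 and 11 (-1.54, 0.0260). With an estimated correlation these 10 lists had adjusted p from 0.668 to 0.778. Without the array labelled Gr control 2 the lymphoid priming (0.169), B lineage (0.314), erythroid (0.0953), megakaryocyte (0.265), interferon (0.0571) and NF-kB (0.0521) lists lost their call and the immediate early list gained one (0.0383), and without Gr control 1 the primary granule list gained one (0.0130). Under the filter on all 8 arrays the T and NK cell (0.0826), megakaryocyte (0.338) and NF-kB (0.0725) lists lost their call, under the mean of probes the lymphoid priming (0.0506), B lineage (0.0571) and megakaryocyte (0.0674) lists, and under the sex term the lymphoid priming (0.152), B lineage (0.394), erythroid (0.0986) and megakaryocyte (0.298) lists. The immediate early list gained a call with no filter (0.0226) and with the sex term (0.0142). The fry function of limma gave an adjusted p from 1.01e-04 to 0.308 for the 11 called lists, under 0.05 for the stem cell, T and NK cell, monocyte, interferon and NF-kB lists. The other 14 lists had camera adjusted p of 0.119 or more, and of these fry gave the adhesion and homing list an adjusted p of 0.0177.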

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

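All weighing tests in this part were chosen after the results they measure were seen, except the test on a further endothelial list, whose genes were written down before it was run.

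The difference of the Vav-Etv2 effect between KSL and Gr cells passed for ENSMUST00000103414 (-6.57), which was well above background on 0 of the 4 Gr arrays and so could not fall there, and, by camera at the preset correlation, for the endothelial (adjusted p = 0.0103), haematopoietic stem cell (1.64e-05) and B lineage (0.0113) lists. With an estimated correlation these lists had adjusted p of 0.980, 0.121 and 0.980. For 8 named genes both Vav-Etv2 arrays lay on one side of both controls in KSL cells and on the opposite side in Gr cells. Their KSL log2 differences were -2.71 for Meg3, 1.97 for Vmn1r212, 2.59 for Tcp10b, 2.08 for Foxn4, -3.45 for Mid1, -2.15 for Sox14, -3.20 for Vnn1 and 0.33 for Lck. Their difference was not tested beyond the interaction, which none of them passed. The naming rule takes genes with the lowest p in the interaction, which favours opposite directions, and the number that chance gives was not computed. Tcp10b, Foxn4, Sox14 and Vnn1 were well above background on 0 of the 4 Gr arrays, so their Gr direction rests on values at background, and for these 4 and Vmn1r212 the lower KSL group was not well above background either, so that the fold is at least 1.97 for Tcp10b, 1.20 for Foxn4, 1.84 for Sox14, 2.29 for Vnn1 and 1.03 for Vmn1r212.

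Etv2 was at least as high in the array labelled Gr control 2 as in the Vav-Etv2 Gr arrays. On the probe not used for the gene it read -0.85, above the -2.33 and -1.88 of the Vav-Etv2 Gr arrays. A fault of 1 probe is argued against by the other Etv2 probe, which read at least 2.94 log2 above Gr control 1, itself not well above background. RNA of these Vav-Etv2 Gr samples, whole or mixed in, is argued against by 13 genes at least 4-fold apart between the labelled groups, against 2 for the crossed split (exact binomial p = 0.00369), where thresholds of 2-, 2.8- and 4-fold were all looked at before the 4-fold one was written. Another Vav-Etv2 mouse under the control label may explain it. Over 100 genes the array lay at a median position of 1.02 between Gr control 1 (0) and the Vav-Etv2 mean (1). This met the criterion first written. Many of the 61 lower genes among them carry transcript identifiers close to those of the 3 immunoglobulin features, and Jchain was another. Such genes may vary together, so they do not count as separate evidence. With the controls exchanged the median was 0.38 over 24 genes, which also goes with it. A condition was added only after that value was seen, because single arrays set many genes apart (167 for Gr control 1 alone, and many for Gr Vav-Etv2 1 alone). That condition leaves the question open. Of the 4 features called in KSL cells, Sva (position 0.04) and ENSMUST00000103416 (-0.08) lay at the control end. The other 2 were not well above background on any Gr array, too few features to decide. The 13 genes against 2 also go against another Vav-Etv2 mouse under the control label, since such a mouse would favour neither split. The tests of this explanation thus point both ways.

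Endothelial genes were high in KSL Vav-Etv2 1 and much less so in replicate 2. Endothelial cells among the sorted cells may be a source, although the sort for lineage-negative c-Kit positive cells is meant to remove most of them: a further endothelial list had a median of 0.771 in that array (20 of 25 genes measured, quartiles -0.407 and 1.84), with 18 of the genes also well above background in both KSL controls. A lower share of neutrophil RNA would raise all other cell types alike and is argued against, since the endothelial list, array 1 minus 2, exceeded the genes of the 11 other cell type lists pooled by 2.10 (quartiles 0.372 and 3.50 against -1.02 and 0.186), although the megakaryocyte list had the same median of 1.62. A first comparison, with the T and NK cell list alone, gave 1.69 with overlapping quartiles, and the pooled one was chosen after it. The pooled lists hold the monocyte (median -0.65), primary granule (-0.69) and mast cell (-1.28) lists, which may fall together with neutrophil RNA and widen the gap. Apart from these and the megakaryocyte list, the medians ran from -0.772 (B lineage) to 0.319 (MHC class II), under the 1.62 of the endothelial list. The higher Etv2 level of that array, by 1.43, is a biological candidate that 2 arrays cannot separate from endothelial cells, so these stay open.

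In KSL cells of Vav-Etv2 mice, which had a mixed strain background, 3 immunoglobulin features fell and Sva rose. Stretches of another strain's genome may do this. The test left out features annotated as immunoglobulin and those without a position on an autosome or X. It therefore cannot speak to the fall of the immunoglobulin features. Among the 72 genes left with an unadjusted p under 0.05 in 1 direction in both cell types, 5 pairs lay within 1 Mb. Random draws gave a median of 4 (permutation p = 0.332, 10000 draws), and as many top genes of control KSL against Gr gave 6. Fewer plasma cells in the samples would lower plasma cell genes that the other sorted cells do not express. The plasma cell list had a median of -0.187 over 14 measured genes (quartiles -1.04 and 0.465), with 8 negative. Jchain, singled out after its value was seen, differed by -3.42. The list was not limited to genes that the other sorted cells lack. Neither test decides, and an effect of Etv2 itself was not tested.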

How the results depend on the processing

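The sex term and both sets of 2 arrays left out were chosen after the data were seen; leaving out 1 array assumes that the lone array of its group varies like the others. The 4 KSL calls were all kept under normexp (16 calls), median scaling (27), quantile normalization (50) and the floor (14), and with a sex term (69); 3 were kept with no filter and with each probe by itself (Sva lost, 0.0546 and 0.0591) and 2 with only the KSL arrays and without the 2 Gr arrays with Y-linked signal (Sva lost, 0.0911, and ENSMUST00000103403, 0.0513, in both), while over all its alternatives Sva ranged from 0.00575 to 0.402. The count was 0 by limma with the filter on all 8 arrays, 0 without KSL Vav-Etv2 1 and the array labelled Gr control 2 (the doubted pair), and 0 to 36 leaving out each array. The Gr count was 0 by limma under normexp, the all-8 filter, only 4 arrays, the replicate block, without the Gr arrays with Y-linked signal (the Y-signal arrays) and without the doubted pair, 1 with no filter, each probe by itself, the intensity trend and the sex term, and 0 to 2 leaving out each array; the single call was ENSMUST00000103416 in the first 3 of these, but with the sex term it was another gene, and ENSMUST00000103416 had 0.0561. With the floor 2 Gr calls remained, but Folr2 was lost (0.125) and another feature took its place. The interaction count was 4 under normexp, 2 under median scaling, 5 under quantile normalization, 4 with the floor, 5 with the sex term, of which ENSMUST00000103414 was 1 except under normexp (0.428) and the floor (0.169), and 0 with no filter, the all-8 filter, the trend, either replicate block, without the Y-signal arrays, without the doubted pair and leaving out each array. KSL against Gr gave 13580 with the sex term, 12100 without the Y-signal arrays and 2201 to 9390 leaving out each array. With an estimated correlation the adjusted p was 0.780 (endothelial), 0.0908 (stem cell) and 0.780 (B lineage) in KSL and 0.848 (B lineage), 0.848 (T and NK) and 0.467 (MHC class II) in Gr cells. Without the doubted pair the KSL neutrophil list turned to higher (0.0394), as did its interaction (1.49e-05), and Gr B lineage gave 0.698; Gr T and NK gave 0.327 without the Y-signal arrays. Leaving out each array the adjusted p ranged, in KSL, from 3.38e-17 to 0.0810 for neutrophil; in Gr, from 2.88e-16 to 0.635 for B lineage, 2.84e-04 to 0.563 for T and NK, 1.43e-04 to 0.622 for megakaryocyte, 1.35e-05 to 0.0586 for MHC class II, 3.57e-05 to 0.731 for proliferation, 2.99e-04 to 0.716 for immediate early and 0.0168 to 0.914 for oxidative phosphorylation; in the interaction, from 8.97e-15 to 0.952 for neutrophil and 5.23e-13 to 0.944 for B lineage. Correlation of KSL and Gr effects was 0.0199 with the all-8 filter, 0.0705 without the Y-signal arrays and 0.0113 to 0.164 leaving out each array. Where fewer arrays or genes were used that is part of the setting. The filter on all 8 arrays removed every feature called in KSL cells, in Gr cells or in the interaction, so its counts of 0 did not retest them. For the other settings the cause was not tested. Of single-gene results outside leaving out 1 array, 1697 kept their side of the threshold and direction, 40 gained and 18 lost a call, where a sign change of a gene called under neither setting counts as kept. A block for slide or scan was not run, as there was 1 of each, and the deposited value table cannot give KSL against Gr. Between 47.7% and 55.5% of probes were well above background, which limits folds of dim genes to bounds.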

Other observations

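The genes in this part were chosen after their values were seen. Ifi202b, of the Ifi200 family, stood at -6.19 and -6.57 in KSL controls and at 2.38 and 2.41 in Vav-Etv2 KSL cells (at least 93.9-fold higher, limma adjusted p = 0.563). It passed without Gr Vav-Etv2 1 or Gr Vav-Etv2 2 (0.0172) and with only the KSL arrays (0.0414), and its limma adjusted p ranged from 0.0172 to 1.00 over all alternatives. In Gr cells it stood at 3.98 in Vav-Etv2 1 and -6.94 in Vav-Etv2 2, with -6.04 in Gr control 1 and -7.19 in the array labelled Gr control 2. Jchain, which joins secreted immunoglobulin, stood at 6.08 and 6.09 in KSL controls and at 1.25 and 4.09 in Vav-Etv2 KSL cells. With a sex term for the Gr arrays, Ifi214 (limma adjusted p = 0.0243) and Meg3 (0.0389) passed in KSL cells, and so did Ifi209 (2.52), Ifi211 (1.85), the Kupffer cell lectin Clec4f (at least 3.04-fold higher) and the lectin Clec1a (at least 3.99-fold lower). Of the genes with an unadjusted p under 0.05 in 1 direction in both cell types, 72 had a position on an autosome or X and no immunoglobulin annotation. Among these 72 were the RNA-binding protein Igf2bp3 (at least 4.78-fold higher in KSL cells, log2 difference 2.25 in Gr cells) and the BMP receptor Bmpr1a (at least 3.02-fold lower in KSL cells, -1.95 in Gr cells). Neither passed the adjusted threshold in either cell type.

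An exchange of the array labelled Gr control 2 with one of the Vav-Etv2 Gr arrays was also looked at and is not among the weighed tests. Etv2 was well above background in both of those arrays and not in Gr control 1, and the lower of them stood at least 2.50 log2 above it.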
